A study of Mus musculus with 8 samples.

How the data were processed

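The submitters extracted total RNA from testes with TRIzol, labelled it with biotin by a 3' in vitro transcription kit and hybridized 1 array per sample, with 8 arrays of 45101 probe sets in 3 groups. As the submitters deposited them, the intensity values had been made by GCRMA, which as generally run corrects background by probe sequence, normalizes between arrays by quantiles and summarizes probes per probe set. Its version and settings are not given in the sources used here. The deposited intensities are on a linear scale, and their log2 was taken here. Detection calls were not used here, and a log2 level of 4, an intensity of 16, served as the floor: a gene was tested if at least 2 arrays reached it.

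Of the probe sets, 34958 carry exactly 1 gene symbol, 932 several and 9211 none listed. Symbols and chromosome membership follow the GRCm38.p6 annotation, in which 34754 probe sets matched by Entrez identifier. For each gene the probe set with the highest mean over all arrays was used, giving 18194 genes, of which 13802 were tested and 4392 left out as low. No listed symbol is Cyp19a1, and as probe sets with none listed were not searched for it, it is not analysed here. Of 107 genes named against control in Sf1-Cre, 29 had another probe set above the floor, and for Jam2 and Kit such a probe set had the opposite sign, in Dhh-Cre as well.

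Groups were compared with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), fitting 3 group means to all 8 arrays (5 residual degrees of freedom, 2.73 prior) with empirical Bayes moderation. The p-values are 2-sided and were adjusted by Benjamini and Hochberg over the 13802 genes, with adjusted p under 0.05 as passing. Errors beside log2 fold changes are limma's standard errors (SE), and those beside group means are standard deviations (SD). Folds against a group whose mean lies under log2 4 are lower bounds against that floor, and no fold is given when both means lie under it. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

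The 21 lists of marker and pathway genes were written before the data were examined, from general knowledge of their expression. They cover Sertoli, granulosa, theca, Leydig, peritubular, fibroblast, endothelial, macrophage, erythroid, epididymal, oocyte, spermatogonial, spermatocyte and spermatid genes, and genes of proliferation, retinoid, TGF-beta and activin, Wnt, tight junction, cholesterol synthesis and housekeeping functions. Each was tested by limma's camera with a preset correlation of 0.01, which asks whether a list moves relative to the other genes, and again with a correlation estimated from the data. Limma's fry, which asks whether a list moves by itself, was an alternative.

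Named genes follow a rule set before the data were examined. It takes fixed genes of gonadal sex, the 10 largest rises and falls per Cre line with every mutant array beyond every control array, the 5 largest each way between the lines, and up to 4 members per list with the lowest p in Sf1-Cre against control. Genes with provisional symbols were passed over. In the comparison of the lines, the list members given with values were narrowed, after their values were seen, to those that passed within called lists. Other members named to spell out a small count, and gene families, were chosen after their values were seen.

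The alternatives changed 1 choice at a time. They were quantile normalization, centring each array on the housekeeping list, no filter or a filter at log2 6, trended robust moderation, array weights, a fit of only the 2 groups compared, the mean of all probe sets of a gene, stricter thresholds, leaving out each array, and, for lists, the estimated correlation, fry and centring on the peritubular and endothelial lists. Replicate numbers were also tried as a block. Setting values under log2 4 to 4, and leaving out the 3 arrays with Spink8 at log2 10 or above, were chosen after seeing the data. Overlap of the Cre lines was set against 100 simulations in which unchanged groups share the 2 controls. In a self-test that added known changes to unchanged simulated data, limma recovered 90% of genes changed by log2 2 in the Sf1-Cre comparison, 76% in the Dhh-Cre comparison and 92% between the lines, and 43%, 6% and 18% of those changed by log2 1. False calls were 5.67%, 10.9% and 3.51% of the genes called. The Leydig list shifted by log2 1 was called by camera (adjusted p = 1.81e-18), with 0 other lists. The simulated genes varied independently, so this does not show how camera behaves with correlated genes. In the data the estimated correlation reached 0.833, in the spermatid list. At most 100 genes were changed per size, where 79.8% of genes passed in Sf1-Cre, so the recovery may differ in the data.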

Results

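Gene expression was measured in whole testes of male mice at postnatal day 28, on 1-colour oligonucleotide arrays of 45101 probe sets. All 8 mice carried 2 floxed copies of Dmrt1, a transcription factor gene of Sertoli and germ cells. The control group carried no Cre recombinase (n = 2), 1 mutant group carried Cre under the Dhh promoter (n = 2) and the other carried Cre under the promoter of Nr5a1, also called Sf1 (n = 4). The submitters describe both drivers as acting in Sertoli cells, the somatic cells that support germ cells inside the seminiferous tubule. Median array intensity was 13.7 to 14.1 in the controls and 15.2 to 15.9 in the mutants, and the share of probe sets at log2 4 or above ran from 47.6% to 49.9%. The small number of arrays limits the precision of every value.

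The Dmrt1 signal was 361 and 433 intensity units in the controls, 1377 and 979 in the arrays labelled Dhh-Cre, and 137, 237, 198 and 185 in those labelled Sf1-Cre. On the log2 scale the means were 8.63 ± 0.18 (SD, n = 2), 10.18 ± 0.35 (SD, n = 2) and 7.54 ± 0.33 (SD, n = 4). Dmrt1 thus fell in the Sf1-Cre arrays (log2 fold change -1.09 ± 0.25 SE, adjusted p = 0.00375, and -2.24 under housekeeping centring) and was higher, not lower, in the arrays labelled Dhh-Cre (1.55 ± 0.28 SE, adjusted p = 0.0012). That second difference was 0.41 with adjusted p = 0.233 once each array was centred on the housekeeping list, against a range of 0.000476 to 0.233 over 19 alternatives. Only 1 Dmrt1 probe set was on the array, and its position relative to the deleted part of the gene is not given in the sources used here. The RNA came from whole testes, so the signal also includes any Dmrt1 RNA of germ cells. Dmrt1 therefore does not bear out the label of the Dhh-Cre arrays, and each direction below that involves them rests on that label.

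Arrays of 1 group resembled each other more than arrays of different groups. Pearson's r of log2 values across probe sets, which are not independent replicates, was 0.994 between the controls, 0.989 between the Dhh-Cre arrays and 0.980 to 0.994 among the Sf1-Cre arrays. Between groups it was 0.804 to 0.838 for control and Dhh-Cre, 0.825 to 0.887 for control and Sf1-Cre, and 0.954 to 0.978 for the 2 mutant groups. The 3' to 5' signal ratios of control transcripts, read as signs of RNA quality, differed between groups but not alike for both transcripts, and whether they reflect RNA quality was not tested. The ratio of Actb, encoding beta-actin, was 4.89 and 4.44 in the controls, 13.6 and 9.51 in the Dhh-Cre arrays and 9.45 to 13.5 in the Sf1-Cre arrays. For Gapdh it was 3.58 and 2.96 in the controls and 1.67 to 3.30 in the mutants, so the groups overlapped. Spink8, a gene of the epididymis, varied within groups. Its log2 level was 6.87 and 3.11 in the controls, 11.55 and 4.48 in the Dhh-Cre arrays and 12.05, 5.79, 10.49 and 6.46 in the Sf1-Cre arrays.

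The Sf1-Cre arrays were compared with the controls to ask which testis transcripts changed under that deletion. Genes of ovarian granulosa cells were among the largest rises. Foxl2os, transcribed opposite to the granulosa transcription factor gene Foxl2, lay at log2 11.37 ± 0.23 (SD, n = 4) against 2.05 ± 0.36 (SD, n = 2), at least 165-fold higher (log2 fold change 9.32 ± 0.21 SE, adjusted p = 2.26e-07). Foxl2 itself was at least 16.2-fold higher (6.15 ± 0.42 SE, adjusted p = 6.17e-06), and Nr5a2, a nuclear receptor gene of granulosa cells, was at least 38.4-fold higher (6.91 ± 0.58 SE, adjusted p = 1.69e-05). Spermatid genes were among the largest falls. Tex55 was at least 186-fold lower (-9.14 ± 0.54 SE, adjusted p = 3.31e-06), and Fam71b was at least 300-fold lower (-8.92 ± 0.53 SE, adjusted p = 3.32e-06).

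**Figure D1:**
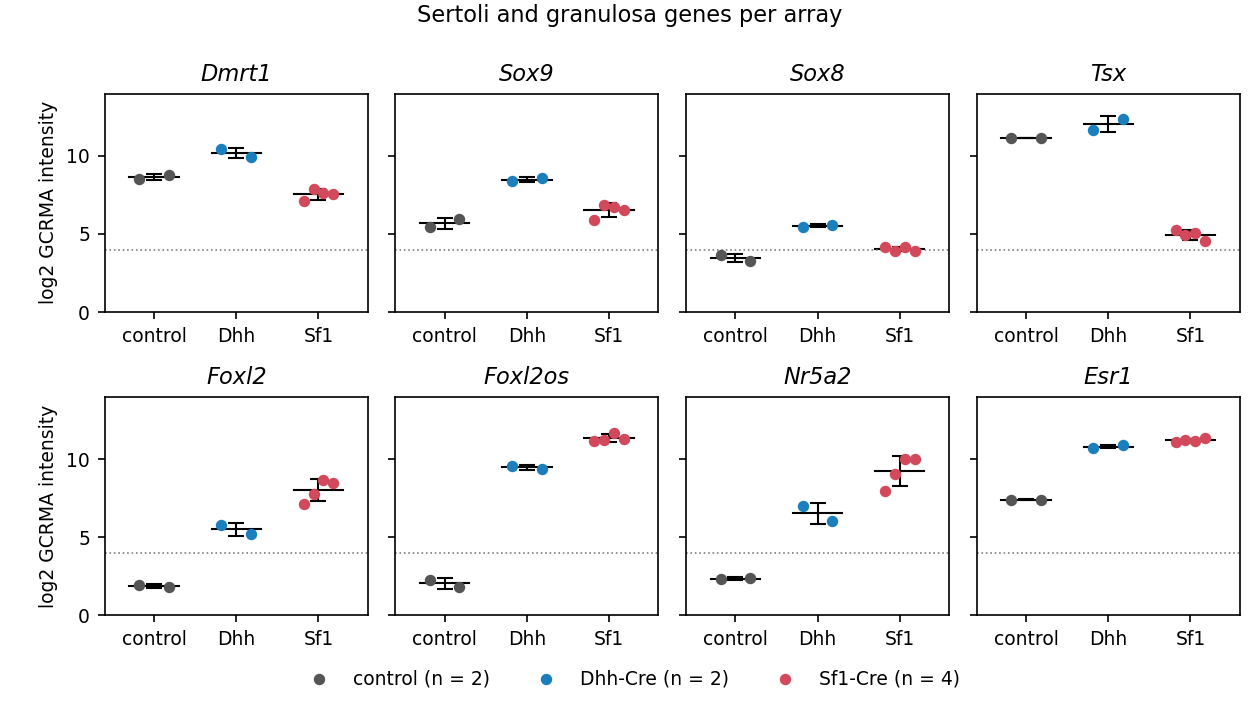
Log2 intensity (vertical axis) of 8 genes in each of the 8 arrays, with dots for arrays and bars for group mean and SD; the dotted line marks log2 4. Foxl2os and Foxl2 lay under log2 4 in both controls and above it in all 6 mutant arrays, while Dmrt1 was highest in the arrays labelled Dhh-Cre, a difference from control that falls to 0.41 under housekeeping centring.

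Other genes fixed for their role in gonadal sex also moved in the Sf1-Cre arrays. Sox9, which drives Sertoli cell fate, was higher by 0.82 ± 0.29 SE (adjusted p = 0.0305) as deposited and lower, at -0.33, under housekeeping centring. It passed in 11 of 19 alternatives, with adjusted p from 0.00198 to 0.305, and missed in each of the fits without control replicate 1 or without Sf1-Cre replicate 2, 3 or 4. Sox8, a Sertoli gene close to Sox9 in sequence, was at least 1.02-fold higher (0.58 ± 0.16 SE, adjusted p = 0.0111) but passed as lower, at -0.57 with adjusted p = 0.0254, under housekeeping centring (range 0.00641 to 0.515 over 18 alternatives), and missed without control replicate 2. Housekeeping centring took the median of that list itself from 0.57 to -0.58, so the sign changes of Sox9 and Sox8 do not show a fall relative to it. Esr1, the estrogen receptor alpha gene, rose 14.1-fold (3.82 ± 0.13 SE, adjusted p = 4.84e-07). The Wnt pathway ligand genes Rspo1 and Wnt4 rose at least 4.68-fold and 3.55-fold. Nr5a1, which encodes a steroidogenic transcription factor, rose by 3.96 ± 0.24 SE. Dhh, a Sertoli cell ligand gene, rose by 1.53 ± 0.15 SE, and by 0.38 with adjusted p = 0.109 under housekeeping centring (range 1.31e-05 to 0.109). Mean levels of Amh and Esr2 lay under log2 4 in all groups, so no fold is given. The remaining largest rises were Sfrp4, Heph, Epdr1, Rsph4a, Ccl12, Bcan, Mdfic and Serpinb6b, with fitted log2 fold changes of 6.58 to 8.61. Heph, a ferroxidase gene, rose 189-fold, and Sfrp4, a secreted Wnt antagonist gene, at least 165-fold. The remaining largest falls were Trp53tg5, Prss52, Cabs1, Oxct2a, H2al2a, Prss37, Actrt3 and Smim23, with fitted values of -8.96 to -8.40, among them Smim23 at least 309-fold lower.

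Spermatid, spermatocyte and oocyte lists fell in the Sf1-Cre arrays. All 35 measured genes of the spermatid list fell, with a median log2 fold change of -4.74 (camera adjusted p = 1.96e-09; adjusted p = 0.466 with an estimated correlation). Among them Tssk6, a testis kinase gene, was at least 116-fold lower (-8.00 ± 0.21 SE), Cst13 at least 96.3-fold lower, Spata18 at least 137-fold and Tssk3 85.8-fold. In the spermatocyte list 19 of 26 genes fell and none rose, with a median of -1.12 (camera adjusted p = 0.000174; adjusted p = 0.466 with an estimated correlation). It was not called after centring on the peritubular and endothelial lists (median -3.81, adjusted p = 0.0754, range 3.82e-05 to 0.466 over 22 alternatives). Smc3, a cohesin gene, fell 6.05-fold, the meiotic recombination gene Msh4 by 3.77 ± 0.38 SE and Ybx2 by 2.75 ± 0.41 SE, and Ovol2 was at least 4.47-fold lower. In the oocyte list, Padi6, Nlrp5, Gdf9 and Figla fell and Nobox did not pass, 4 of 5, with a median of -1.84, or -1.82 with values under log2 4 set to 4 (camera adjusted p = 0.0357; adjusted p = 0.466 with an estimated correlation). The oocyte list was not called under housekeeping centring (median -2.98, adjusted p = 0.117) or after the peritubular and endothelial centring (-4.52, adjusted p = 0.237), and passed in 17 of 22 alternatives (adjusted p 0.000152 to 0.466). Only 5 of 12 oocyte genes on the array were tested, and 4 of these lay at log2 4 or above in the controls, which can favour falls. The controls are testes, so the fall of this list says nothing on oocytes. Of 16 spermatogonia genes, 6 rose and 5 fell (camera adjusted p = 0.98), and the median of 0.27, -0.88 under housekeeping centring, had the opposite sign to the test. Foxo1 rose by 1.78 ± 0.12 SE, Gfra1, the GDNF co-receptor gene of stem spermatogonia, fell to a mean under log2 4, and Zbtb16 rose by 1.19, with 0.04 and adjusted p = 0.851 under housekeeping centring (range 4.46e-05 to 0.851). Kit was at least 3.99-fold higher by the probe set used, but its other probe set gave -0.77. For each list in this comparison the count of rises and falls adjusted over the list alone equalled the count over all genes.

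Granulosa genes rose beside this loss of spermatid signal. In the granulosa list 18 of 23 genes rose and Irx5, Lhx2 and Lef1 fell, with a median of 3.21, 2.45 with values under log2 4 set to 4, 2.06 under housekeeping centring and 0.53 after the peritubular and endothelial centring (camera adjusted p = 0.00667; adjusted p = 0.466 with an estimated correlation). Inha, the inhibin alpha gene, rose by 2.80 ± 0.13 SE and Irx5 was at least 14.9-fold lower. Members named only for a small count, such as Lhx2 and Lef1, were chosen after their values were seen. Of the 23 granulosa genes, 10 also stand in another list and 10 lay at log2 4 or above in the controls. Among other lists, 3 of 9 endothelial, 8 of 17 Wnt and 12 of 22 TGF-beta and activin genes lay there. Genes under that level in the controls were tested mainly because mutant arrays reached it, which favours rises in such lists. In the Sertoli list 14 of 25 genes rose and Tsx, Rhox5, Cst9, Fgf9 and Hopx fell, with a median of 0.74 as deposited and -0.41 under housekeeping centring (camera adjusted p = 0.25). Gata4, shared by Sertoli and other gonadal somatic cells, rose by 4.54 ± 0.26 SE, Abcb1a by 3.93 ± 0.27 SE and Ctsl by 1.93 ± 0.13 SE, while the X-linked gene Tsx fell 74.3-fold (-6.22 ± 0.26 SE). Of 16 tight junction genes 6 rose and Nectin3, Cldn3, Ocln and Cdh2 fell (median 0.27, -0.88 under housekeeping centring, camera adjusted p = 0.644), with F11r at 3.45 ± 0.28 SE, Cldn5 at 3.42 ± 0.33 SE, Cxadr at least 4.93-fold higher and Jam2 at 2.85 ± 0.21 SE, another Jam2 probe set giving -0.28.

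Macrophage and other interstitial lists rose in the same Sf1-Cre arrays, whose Actb 3' to 5' ratio was 9.45 to 13.5 against 4.44 and 4.89 in the controls. In whole testes, a larger share of somatic RNA after the loss of germ cell RNA could raise such lists. That share was not separated from changes within cells here or in the other somatic lists. All 18 macrophage genes rose, with a median of 4.07, 2.92 under housekeeping centring and 1.39 after centring on the peritubular and endothelial lists (camera adjusted p = 9.04e-07; adjusted p = 0.377 with an estimated correlation). Cd74, the invariant chain gene of antigen presentation, rose 34.7-fold (5.12 ± 0.18 SE), and H2-Aa, Tyrobp and Lyz2 rose 24.0-fold, 23.9-fold and 19.4-fold. In the Leydig list 11 of 12 genes rose, with a median of 2.21, 1.91 with low values set to log2 4 and -0.47 after centring on the peritubular and endothelial lists (camera adjusted p = 0.00524; adjusted p = 0.466 with an estimated correlation). Hsd3b1, a steroidogenic enzyme gene, rose 7.21-fold, Akr1c14 37.5-fold and Vcam1 18.5-fold. In the fibroblast list 11 of 13 genes rose, with a median of 2.43, and -0.25 after that centring (camera adjusted p = 0.00524; adjusted p = 0.377 with an estimated correlation). Dcn, the decorin gene, rose by 5.57 ± 0.17 SE, Igf1 by 4.62, Tcf21 by 4.48 and Col3a1 by 3.88. All 9 endothelial genes rose, with a median of 2.00, 1.82 with low values set to log2 4 and -0.68 after that centring (camera adjusted p = 0.0162; adjusted p = 0.466 with an estimated correlation), including Robo4 at least 11.1-fold, Emcn at least 11.1-fold and Esam at least 3.54-fold. Only 3 of these 9 lay at log2 4 or above in the controls, which favours rises among the genes tested. All 7 theca genes rose, with a median of 1.73, 1.22 with low values set to log2 4 and -0.95 after that centring (camera adjusted p = 0.0324; adjusted p = 0.466 with an estimated correlation), including Nr2f2 by 2.57, Ptch1 by 1.73 and Enpep at least 2.08-fold.

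Signalling lists followed in the Sf1-Cre arrays. In the TGF-beta and activin list 19 of 22 genes rose and Smad6 and Bmp7 fell, with a median of 2.19, 1.43 with low values set to log2 4 and -0.50 after the peritubular and endothelial centring (camera adjusted p = 0.00524; adjusted p = 0.466 with an estimated correlation). Id3 was at least 10.2-fold higher, Bmp4 at least 2.54-fold higher and Smad6 at least 11.6-fold lower. In the Wnt list 13 of 17 genes rose and Lef1 fell, with a median of 1.92, 0.94 with low values set to log2 4 and -0.76 after that centring (camera adjusted p = 0.0409; adjusted p = 0.466 with an estimated correlation). Fzd2 rose 32.2-fold, Wnt6 20.4-fold and Fzd1 at least 5.31-fold. In the housekeeping list 12 of 16 genes rose and Tbp fell, with a median of 0.57, and -0.58 when centred on itself (camera adjusted p = 0.0332; adjusted p = 0.466 with an estimated correlation). Gusb rose by 3.27, B2m by 2.63, Sdha by 1.77 and Pgk1 by 1.69. The other lists were not called. Cholesterol synthesis held 11 rises and 1 fall, Cyp51, among 16 genes (median 1.30, camera adjusted p = 0.0667), with Msmo1 at 3.86, Sc5d at 3.04, Nsdhl at 2.79 and Insig1 at 1.54, the last 0.39 and not passing under housekeeping centring. The retinoid list held 9 rises and 1 fall, Stra6, among 13 (median 1.10, -0.05 under housekeeping centring, camera adjusted p = 0.0869), with Dhrs3 at 4.07, Aldh1a3 at 2.95, Tgm2 4.29-fold higher and Aldh1a1 at 1.22, 0.07 and not passing under housekeeping centring. The peritubular list held 10 rises and 1 fall among 12 (median 1.28, -1.40 when centred with the endothelial list, camera adjusted p = 0.106), with Myl9 at 1.94, Tagln at 1.87, Acta2 at 1.51 (0.36 and not passing under housekeeping centring) and Actg2 at -4.81. The Wnt list was not called without control replicate 2 (adjusted p = 0.0628).

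The last 3 lists in this comparison showed mixed directions. Proliferation genes split into 4 rises and 7 falls of 19 (median -0.20, camera adjusted p = 0.25), the rises being Tk1, Mcm2, Mki67 and Mcm5. The mitotic genes Plk1 and Ccnb2 fell by 2.05 and 1.71, and the replication genes Tk1 and Mcm2 rose by 2.31 and 1.36, the latter 0.21 and not passing under housekeeping centring. Of 3 erythroid genes, Hbb-b2 rose by 1.79 while Hba-a2 and Alas2 fell by 2.16 and 1.52 (median -1.52, camera adjusted p = 0.613), and Alas2 missed without control replicate 1 (adjusted p = 0.0525). Of 4 epididymal genes, Defb15 rose by 0.95, at -0.20 under housekeeping centring, and Ros1 was at least 1.17-fold lower, not passing with low values set to log2 4. Spink8 at 3.71 ± 2.42 SE (adjusted p = 0.188, range 0.0075 to 0.627 over 19 alternatives) did not pass, except with replicate numbers as a block. Adam7, whose means lay under log2 4, did not pass either (adjusted p = 0.474). The epididymis list had a median of 1.16 with the opposite sign to its test (camera adjusted p = 0.895).

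In all, 11020 of 13802 tested genes, 79.8%, passed limma's test between Sf1-Cre and control arrays (11194 at an unadjusted p under 0.05). Of these 6434 were higher and 4586 lower, and 8395 differed at least 2-fold. Centring on the housekeeping list moved the median of all genes from 0.34 to -0.81 and turned the split to 3148 higher and 7867 lower, so the share of higher genes went from 58.4% to 28.6%. Centring subtracts 1 value per array, the median level of the list used, so it moves every gene of a comparison by the same step. In Sf1-Cre that step exceeded the lists' own median changes. The housekeeping median went from 0.57 to -0.58, the peritubular from 1.28 to -1.40 and the endothelial from 2.00 to -0.68. The housekeeping list was also called up itself. A sign turned by either centring thus does not by itself show a gene or list lagging behind the lists used. After centring on the peritubular and endothelial lists, camera still called 5 of the 7 called lists whose median turned negative up, and not the housekeeping and theca lists. Camera compares a list with the other genes, which centring moves alike, so a kept call is no separate support for a rise. Of the 21 lists, 12 were called, 9 up and 3 down, and none with an estimated correlation, where fry, which tests whether a list moves on balance 1 way, called 18.

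**Figure D2:**
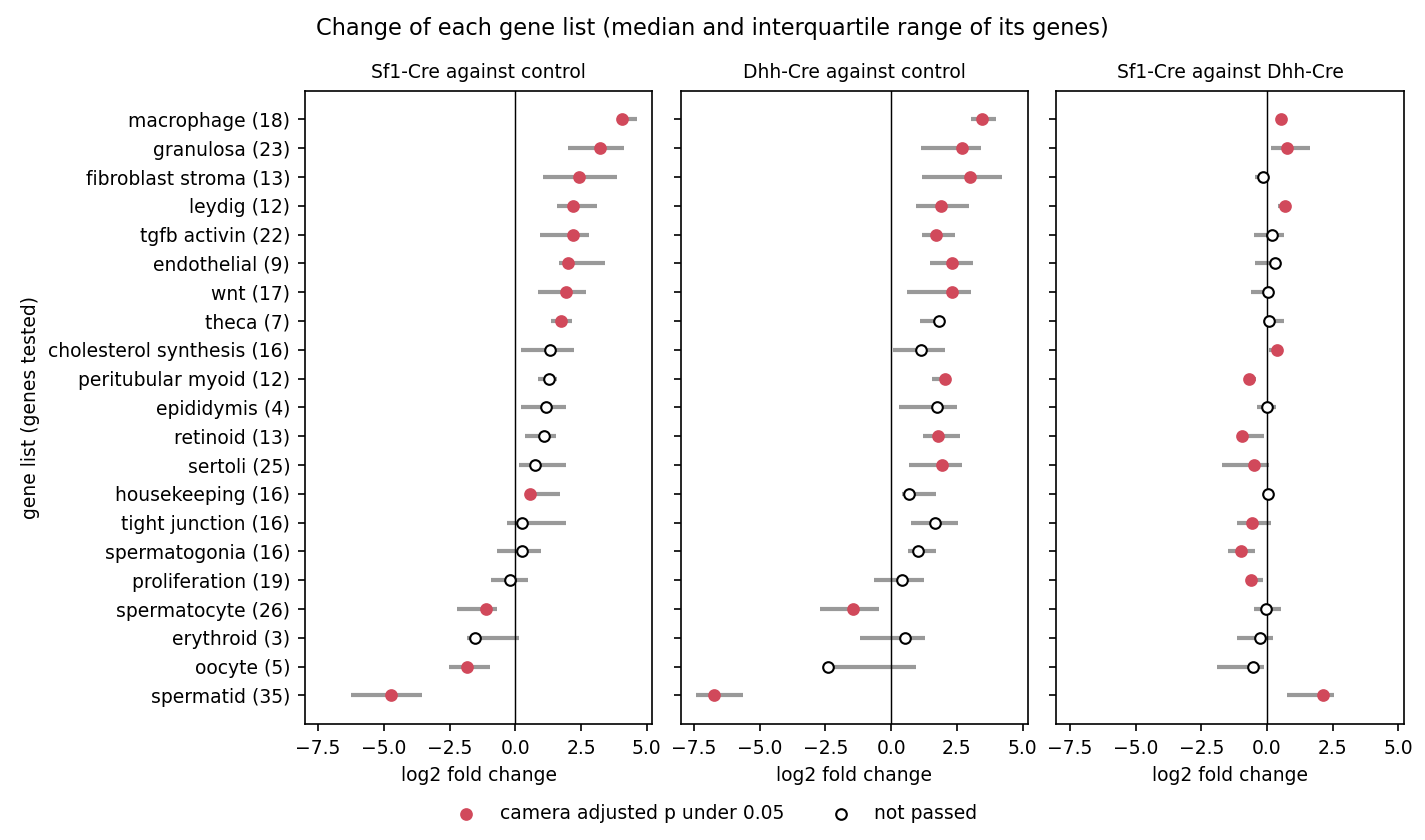
Median (point) and interquartile range (line) of log2 fold changes of each of the 21 gene lists (vertical axis) in the 3 comparisons, with filled points where camera's adjusted p was under 0.05. The spermatid list lay lowest, at -4.74 and -6.76 against control, and the macrophage list highest, at 4.07 and 3.47. Medians of several somatic lists turn negative when arrays are centred on the peritubular and endothelial lists. One is that of the Sertoli list in Dhh-Cre, at -0.76, still called up by camera, which compares a list with the other genes. That centring also turns the medians of both lists used negative, so such a sign does not by itself show a lag behind them.

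The arrays labelled Dhh-Cre were compared with the same controls to ask the same question with the other driver, with the limit that Dmrt1 was not lower in them. Sertoli genes were higher in these arrays. Sox9 was 6.88-fold higher (2.78 ± 0.34 SE, adjusted p = 0.000127), at log2 8.47 ± 0.15 (SD, n = 2) against 5.69 ± 0.35 (SD, n = 2), and Sox8 at least 2.89-fold higher (2.08 ± 0.19 SE, adjusted p = 3.01e-05). Granulosa genes rose too, with Foxl2os at least 45.2-fold (7.45 ± 0.24 SE, adjusted p = 1.23e-06) and Foxl2 at least 2.88-fold higher (3.65 ± 0.48 SE, adjusted p = 0.000209). Spermatid genes again fell, among them Aldoart1, a sperm aldolase gene, at least 258-fold lower (-8.57 ± 1.11 SE, adjusted p = 0.000185).

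Among the other fixed genes, Esr1 rose 10.7-fold in the arrays labelled Dhh-Cre (3.41 ± 0.15 SE, adjusted p = 2.09e-06), Nr5a1 by 3.04 ± 0.28 SE and Dhh by 2.18 ± 0.18 SE. Wnt4 and Rspo1 rose at least 5.93-fold and 3.93-fold. Wfdc18 rose 212-fold (7.73 ± 0.28 SE, adjusted p = 1.49e-06). Shisa4, Myoz2, Ang, Car3, Procr, Serpinb6b, Hspb8 and Robo4 had fitted log2 fold changes of 5.80 to 7.09, among them Ang, the angiogenin gene, at least 26.6-fold, and Robo4, an endothelial receptor gene, at least 52.7-fold. The largest fitted falls after Aldoart1 were Lrrc74a, Tmem225, Vwa3b, Spertl, Ccin, Tmem190, Tex24, Tex55 and Ccdc70, at -8.49 to -8.29. Ccin, encoding the sperm head protein calicin, was at least 118-fold lower.

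Spermatid and spermatocyte lists fell in the arrays labelled Dhh-Cre as well. In the spermatid list 34 of 35 genes fell and Prm1 did not pass, with a median of -6.76, or -6.55 with values under log2 4 set to 4 (camera adjusted p = 2.04e-11; adjusted p = 0.417 with an estimated correlation). Tssk6 was at least 116-fold lower, Cst13 at least 96.3-fold, Spata18 at least 137-fold and Tssk3 at least 93.8-fold. In the spermatocyte list 15 of 26 genes fell and Dmc1 and Tex101 rose, or 14 and 2 adjusted over the list alone, with a median of -1.46 (camera adjusted p = 6e-04; adjusted p = 0.439 with an estimated correlation). Smc3 fell by 2.34, Msh4 by 3.13, Ybx2 by 3.19 and Ovol2 was at least 4.47-fold lower. Of 16 spermatogonia genes 10 rose and Gfra1 and Id4 fell (median 1.03, -0.12 under housekeeping centring, camera adjusted p = 0.139). Foxo1 rose by 1.76, Zbtb16 was at 0.76 but -0.39 under housekeeping centring, and Kit, whose means lay under log2 4, did not pass (adjusted p = 0.398) and passed as lower under housekeeping centring, at -0.79, and by its other probe set, at -1.73. Of 5 oocyte genes, Padi6, Gdf9 and Nlrp5 fell, by at least 29.5-fold and 3.91-fold for the first pair and by 2.40, and Figla at 0.95, -0.20 under housekeeping centring, and Nobox were higher (median -2.40, camera adjusted p = 0.236). In this comparison the counts adjusted over the list alone equalled those over all genes except for the spermatocyte, theca and housekeeping lists.

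Sertoli, peritubular and retinoid lists were called up beside this loss of spermatid signal in the arrays labelled Dhh-Cre. In the Sertoli list 20 of 25 genes rose and Fgf9 fell, with a median of 1.93, 1.53 with low values set to log2 4 and -0.76 after the peritubular and endothelial centring (camera adjusted p = 0.00888; adjusted p = 0.417 with an estimated correlation). Gata4 rose by 4.14, Abcb1a by 3.26 and Ctsl by 2.04. Tsx was at 0.88 ± 0.29 SE but -0.27 under housekeeping centring, with adjusted p from 0.00893 to 0.503 over 19 alternatives, and missed without Dhh-Cre replicate 2 or either control. Of 12 peritubular genes 10 rose and Actg2 fell, with a median of 2.04, and -0.64 after that centring (camera adjusted p = 0.0466; adjusted p = 0.417 with an estimated correlation). The peritubular list was not called without control replicate 1 or Dhh-Cre replicate 2 (adjusted p = 0.0623 and 0.0612). Acta2 rose by 2.17, Tagln by 2.53 and Myl9 by 2.32, and Actg2 fell by 4.03. Of 13 retinoid genes 11 rose and Aldh1a2 fell, with a median of 1.77, and -0.91 after that centring (camera adjusted p = 0.0165; adjusted p = 0.417 with an estimated correlation). Aldh1a3, a retinoic acid synthesis gene, rose 14.8-fold, Dhrs3 13.8-fold, Tgm2 6.04-fold and Aldh1a1 2.29-fold, the last at 0.05 with adjusted p = 0.786 under housekeeping centring (range 2.37e-06 to 0.786).

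Macrophage and interstitial lists rose in the arrays labelled Dhh-Cre, whose Actb 3' to 5' ratios were 13.6 and 9.51. As in Sf1-Cre, a larger share of somatic RNA after the loss of germ cell RNA was not separated from changes within cells. All 18 macrophage genes rose, with a median of 3.47, 3.42 with low values set to log2 4, 2.33 under housekeeping centring and 0.79 after the peritubular and endothelial centring (camera adjusted p = 1.21e-05; adjusted p = 0.414 with an estimated correlation), Cd74 by 4.80, H2-Aa by 4.23, Tyrobp by 4.03 and Lyz2 by 3.26. Of 13 fibroblast genes 11 rose and Postn fell, with a median of 3.02, 1.87 under housekeeping centring and 0.33 after that centring on the 2 lists (camera adjusted p = 0.00888; adjusted p = 0.414 with an estimated correlation), Dcn rising by 4.87, Igf1 by 4.78, Tcf21 by 4.37 and Col3a1 by 4.23. All 9 endothelial genes rose, with a median of 2.32, 1.30 with low values set to log2 4 and -0.36 after the peritubular and endothelial centring (camera adjusted p = 0.0328; adjusted p = 0.439 with an estimated correlation), Emcn at least 5.52-fold, Esam at least 2.46-fold and Cldn5 8.57-fold. Here too only 3 of the 9 lay at log2 4 or above in the controls. Of 12 Leydig genes 9 rose, with a median of 1.89, 1.78 with low values set to log2 4 and -0.80 after that centring (camera adjusted p = 0.038; adjusted p = 0.417 with an estimated correlation), Akr1c14 by 4.42, Vcam1 by 3.27 and Hsd3b1 by 2.59. Of 23 granulosa genes 16 rose and Irx5, Lef1 and Lhx2 fell, with a median of 2.69, 2.20 with low values set to log2 4, 1.55 under housekeeping centring and 0.01 after the peritubular and endothelial centring (camera adjusted p = 0.0362; adjusted p = 0.439 with an estimated correlation), Inha rising by 2.44 and Irx5 at least 14.9-fold lower. With low values set to log2 4 the endothelial and granulosa lists were no longer called, and without Dhh-Cre replicate 2 the Leydig list was not (adjusted p = 0.0656).

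Of 22 TGF-beta and activin genes in the arrays labelled Dhh-Cre, 17 rose and Smad6 fell, with a median of 1.69, 1.39 with low values set to log2 4 and -0.99 after the peritubular and endothelial centring (camera adjusted p = 0.00888; adjusted p = 0.417 with an estimated correlation). Id3 was at least 9.33-fold and Bmp4 at least 2.40-fold higher, and Smad6 at least 11.6-fold lower. Of 17 Wnt genes 13 rose and Lef1 fell, with a median of 2.33, 1.81 with low values set to log2 4 and -0.36 after that centring (camera adjusted p = 0.0466; adjusted p = 0.417 with an estimated correlation), with Wnt6 at 4.30, Fzd2 at 3.52 and Fzd1 at least 6.87-fold higher. The Wnt list was not called without control replicate 2 or with low values set to log2 4, and the theca list was called without Dhh-Cre replicate 1 (adjusted p = 0.0435). The remaining lists were not called. Theca genes held 6 rises of 7, or 7 adjusted over the list alone (median 1.82, 0.99 with low values set to log2 4, camera adjusted p = 0.0568), with Nr2f2 at 2.08, Ptch1 at 1.99 and Enpep, whose mean lay under log2 4 in both groups, given no fold. Housekeeping genes held 12 rises of 16, or 13 adjusted over the list alone, and 1 fall, Tbp (median 0.68, -0.46 when centred on itself, camera adjusted p = 0.0568), with Gusb at 2.38, B2m at 2.28, Pgk1 at 1.78 and Sdha at 1.71. Of 16 tight junction genes 13 rose and Nectin3 and Cdh2 fell (median 1.68, camera adjusted p = 0.0873), with F11r at 4.10, Jam2 at 2.93 (other probe sets giving -0.20 and -0.39), Cldn5 at 3.10 and Cxadr at least 3.17-fold higher. Of 16 cholesterol synthesis genes 10 rose and Fdft1 and Cyp51 fell (median 1.15, camera adjusted p = 0.305), with Msmo1 at 3.25, Sc5d at 2.55, Nsdhl 5.09-fold higher and Insig1 at 1.14, the last at -0.01 under housekeeping centring. Proliferation genes held 7 rises and 5 falls of 19 (median 0.43, -0.72 under housekeeping centring, camera adjusted p = 0.869), the median having the opposite sign to the test. Plk1 and Ccnb2 fell by 2.00 and 2.07, and Tk1 and Mcm2 rose by 3.18 and 2.08.

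Of 3 erythroid genes in the arrays labelled Dhh-Cre, Hbb-b2 rose by 2.04, Hba-a2 fell by 2.88, and Alas2 at 0.54 ± 0.45 SE, -0.60 under housekeeping centring, did not pass (median 0.54, opposite in sign to the mean and the test, camera adjusted p = 0.92). Of 4 epididymal genes, Defb15 was at 1.14, with -0.004 under housekeeping centring, and Ros1 at least 1.17-fold lower, not passing with low values set to log2 4. Spink8 at 3.03 ± 2.79 SE (adjusted p = 0.342, range 0.0164 to 0.878 over 19 alternatives) did not pass, except with replicate numbers as a block. Adam7, at least 1.69-fold higher (adjusted p = 0.291, range 0.0283 to 0.813 over 19 alternatives), did not pass, except without Dhh-Cre replicate 2. Without Dhh-Cre replicate 1 both turned lower, at -0.51 and -0.48. The epididymis list had a median of 1.75, opposite in sign to the test (camera adjusted p = 0.869).

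Between the arrays labelled Dhh-Cre and the controls 10987 genes passed, 79.6% of those tested (11143 at an unadjusted p under 0.05), with 6781 higher, 4206 lower and 8923 at least 2-fold. Housekeeping centring moved the median of all genes from 0.54 to -0.61 and the split to 3329 higher and 6962 lower, a share of higher genes of 32.3% in place of 61.7%. Of the 21 lists 12 were called, 10 up and 2 down, none with an estimated correlation, and fry called 18. After centring on the peritubular and endothelial lists, 6 of the 7 called lists whose median turned negative were still called up by camera, and the peritubular list was not. As in Sf1-Cre, such kept calls are no separate support for a rise.

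The Sf1-Cre arrays were then compared with the arrays labelled Dhh-Cre, to ask where the drivers differed. Sertoli genes were lower and granulosa genes higher in Sf1-Cre. Sox9 was 3.89-fold lower (-1.96 ± 0.29 SE, adjusted p = 0.00372), Sox8 2.82-fold lower (-1.50 ± 0.16 SE, adjusted p = 0.00108) and Dmrt1 6.25-fold lower (-2.64 ± 0.25 SE, adjusted p = 0.00054). Foxl2 was 5.64-fold higher (2.49 ± 0.42 SE, adjusted p = 0.00599) and Foxl2os 3.65-fold higher (1.87 ± 0.21 SE, adjusted p = 0.00121). Lpar3, a lysophosphatidic acid receptor gene, lay at log2 2.16 ± 0.12 (SD, n = 4) against 10.47 ± 0.09 (SD, n = 2), at least 88.9-fold lower (-8.31 ± 0.14 SE, adjusted p = 1.88e-07).

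Other large differences in Sf1-Cre were falls of Tsx (136-fold), Wfdc18 (116-fold), Tbx22 (at least 28.1-fold) and Cep85 (58.7-fold), and rises of Ptchd3 (25.6-fold), Sfrp4 (22.4-fold), Glipr1l1 (at least 10.8-fold) and Clec7a (at least 7.43-fold). The fall of Cep85 holds for the probe set used only, as its other probe set, also above the floor, gave -0.19. Clec7a encodes dectin-1, a receptor of myeloid cells. Xaf1, an interferon-induced gene, was at least 28.4-fold higher (5.72 ± 0.21 SE) by the probe set used, but its other probe set gave -5.34, and their mean gave 0.19 with adjusted p = 0.567 (range 3.71e-06 to 0.567), so its direction is not settled. Nr5a1 was at 0.92 ± 0.24 SE (adjusted p = 0.03, 0.00742 to 0.146 over 19 alternatives) and missed without any 1 array except Sf1-Cre replicates 1 and 4. Dhh was at -0.65 ± 0.15 SE (adjusted p = 0.0203, 0.0148 to 0.161 over 19 alternatives) and missed without either Dhh-Cre array or Sf1-Cre replicate 2. Wnt4 at -0.74 ± 0.51 SE (adjusted p = 0.329; 0.31 with the 3 arrays highest in Spink8 left out), Rspo1 at 0.25 ± 0.22 SE (adjusted p = 0.449) and Esr1 at 0.41 ± 0.13 SE (adjusted p = 0.0614) did not pass. Cep85 missed without Dhh-Cre replicate 1 or the 3 arrays highest in Spink8, over a range of 5.55e-05 to 0.118.

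In the Sertoli list 14 of 25 genes were lower in Sf1-Cre than in the arrays labelled Dhh-Cre and Mro and Ptgds higher, the same counts adjusted over the list alone, with a median of -0.51 (camera adjusted p = 0.000424; adjusted p = 0.259 with an estimated correlation). In the granulosa list 8 of 23 were higher and Nr0b1 lower, or 14 and 2 adjusted over the list alone, with a median of 0.78, or 0.77 with low values set to log2 4 (camera adjusted p = 0.0014; adjusted p = 0.444 with an estimated correlation). Tight junction genes were lower in 7 of 16 and higher for Nectin3, or 7 and 3 adjusted over the list alone, with a median of -0.59, or -0.55 with low values set to log2 4 (camera adjusted p = 0.0232; adjusted p = 0.259 with an estimated correlation). Retinoid genes were lower in 8 of 13 and higher for Aldh1a2, the same adjusted over the list alone, with a median of -0.94 (camera adjusted p = 0.0014; adjusted p = 0.315 with an estimated correlation), including Aldh1a3 at -0.94 ± 0.24 SE and Tgm2 at -0.49 ± 0.12 SE. Peritubular genes were lower in 6 of 12, or 7 with 1 higher adjusted over the list alone, with a median of -0.67 (camera adjusted p = 0.0014; adjusted p = 0.259 with an estimated correlation), including Acta2 at -0.67 ± 0.13 SE and Actg2 at -0.78 ± 0.24 SE. Of these, Acta2 also missed without Dhh-Cre replicate 1, Tgm2 without that array or Sf1-Cre replicate 2, Aldh1a3 without Sf1-Cre replicate 2 or 3, and Actg2 without any 1 array except Sf1-Cre replicate 1. Aldh1a3, Tgm2, Acta2 and Actg2 each missed the threshold without Dhh-Cre replicate 2, at adjusted p = 0.157, 0.0959, 0.0592 and 0.262, where over all alternatives their adjusted p ran from 0.00252 to 0.327.

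Germ cell lists differed between the lines in both directions, while the Spink8 level differed more within each line than between them. Spermatid genes were higher in 13 of 35 and lower for Prm1 in Sf1-Cre, or 20 and 3 adjusted over the list alone, with a median of 2.12, or 1.68 with low values set to log2 4 (camera adjusted p = 0.000424; adjusted p = 0.662 with an estimated correlation). That median was 1.09 without Dhh-Cre replicate 1 and 0.71 with the 3 arrays highest in Spink8 left out, and the list was not called in either. Without Dhh-Cre replicate 1 the tight junction, proliferation, Leydig and cholesterol synthesis lists were not called either, the last also not without Dhh-Cre replicate 2 or Sf1-Cre replicate 4. Spermatogonia genes were lower in 8 of 16 and higher for Kit, or 10 and 2 adjusted over the list alone, with a median of -0.97, or -0.91 with low values set to log2 4 (camera adjusted p = 0.0014; adjusted p = 0.259 with an estimated correlation). Kit was at least 3.99-fold higher (2.42 ± 0.32 SE, adjusted p = 0.00247). Proliferation genes were lower in 5 of 19, Mcm3, Mki67, Cdk1, Mcm6 and Mcm5, or 8 adjusted over the list alone, with a median of -0.60 (camera adjusted p = 0.00619; adjusted p = 0.444 with an estimated correlation). Spermatocyte genes held 6 rises and 2 falls, Dmc1 and Msh5, of 26 with the same counts adjusted over the list alone (median -0.02, opposite in sign to the mean and the test, camera adjusted p = 0.956). Of 5 oocyte genes Gdf9 was higher and Nobox and Figla lower (median -0.54, camera adjusted p = 0.157).

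Among interstitial lists, macrophage genes were higher in 7 of 18 in Sf1-Cre, or 9 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 0.000424; adjusted p = 0.259 with an estimated correlation), including Lyz2 at 1.02 ± 0.15 SE, not passing with the 3 arrays highest in Spink8 left out, and Tyrobp at 0.55 ± 0.15 SE, the latter with adjusted p from 0.0147 to 0.177 over 19 alternatives and missing without any 1 array except Sf1-Cre replicate 1. Leydig genes were higher for Hsd11b1, Nr5a1 and Gramd1b and lower for Star of 12, or 5 and 1 adjusted over the list alone, with a median of 0.68 (camera adjusted p = 0.0221; adjusted p = 0.444 with an estimated correlation). Cholesterol synthesis genes were higher for Sqle, Fdft1 and Fdps of 16, or 5 adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.043; adjusted p = 0.58 with an estimated correlation). Lists that were not called had medians of -0.54 to 0.32. Endothelial genes held 2 rises, Emcn and Tek, and 2 falls, Robo4 and Plvap, of 9 (median 0.32, opposite in sign to the mean, camera adjusted p = 0.996). TGF-beta and activin genes held 2 rises, Fst and Bmpr1b, and 5 falls of 22, or 6 and 7 adjusted over the list alone (median 0.18, camera adjusted p = 0.842). Wnt genes held 1 rise, Fzd2, and 4 falls, Dkk3, Sfrp1, Wnt9a and Nkd1, of 17 (median 0.04, opposite in sign to the mean and the test, camera adjusted p = 0.595). Fibroblast genes held Dcn higher and Mfap4 lower of 13, the latter lost adjusted over the list alone (median -0.16, camera adjusted p = 0.243). Theca genes held Enpep higher of 7 (median 0.09, camera adjusted p = 0.649), erythroid genes Alas2 lower of 3 (median -0.25, camera adjusted p = 0.595), housekeeping genes Gusb higher of 16 and 0 adjusted over the list alone (median 0.03, camera adjusted p = 0.742), and of 4 epididymal genes 0 passed (median 0.02, opposite in sign to the mean and the test, camera adjusted p = 0.956).

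Between the mutant groups 3402 genes passed, 24.6% of those tested (5257 at an unadjusted p under 0.05), 1778 higher and 1624 lower in Sf1-Cre, with 2101 at least 2-fold. Leaving out the 3 arrays highest in Spink8 removes Dhh-Cre replicate 1 and Sf1-Cre replicates 1 and 3, and keeps 5 arrays. Dhh-Cre replicate 2 is then the lone array of its group, so a lower count cannot be tied to Spink8. The count was 1234 without Dhh-Cre replicate 1, 2201 without Dhh-Cre replicate 2, and 816 with the 3 arrays highest in Spink8 left out. Of the 21 lists 11 were called, 5 up and 6 down, with 6 without Dhh-Cre replicate 1, none with an estimated correlation and 10 by fry.

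**Figure D3:**
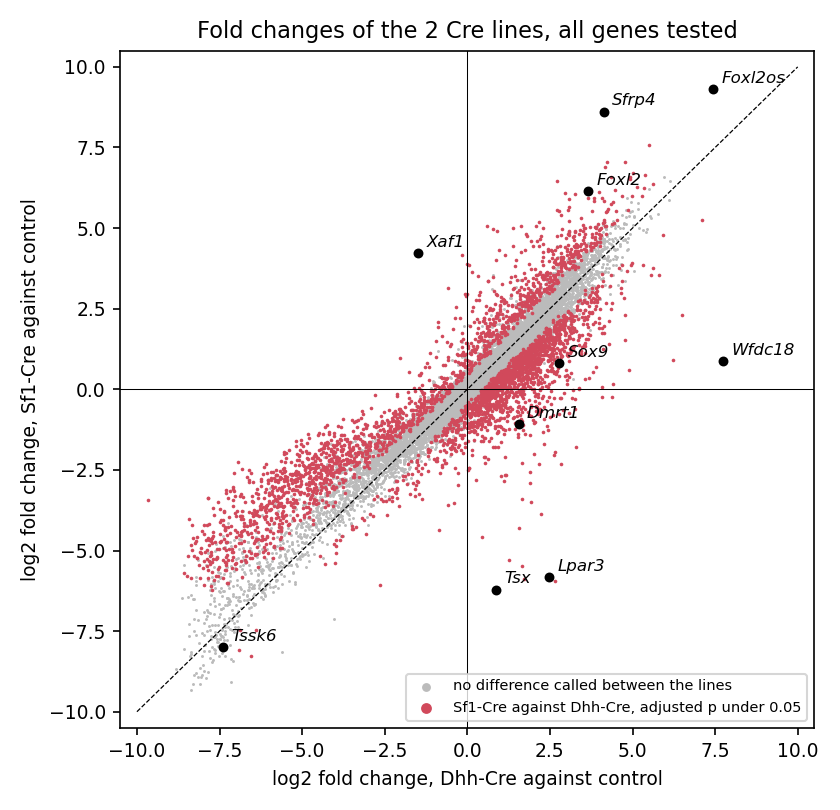
Log2 fold change against control of 13802 genes in the Sf1-Cre arrays (vertical axis) and the arrays labelled Dhh-Cre (horizontal axis), each dot 1 gene, red where the lines differed at adjusted p under 0.05 (3402 genes), with the dashed line marking equal change. Most genes lie along that line, while Lpar3, Tsx and Wfdc18 lie far below it; under housekeeping centring the Tsx value in Dhh-Cre turns from 0.88 to -0.27.

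Against the shared controls, 9872 genes passed in the same direction in both lines, 5929 higher and 3943 lower, and 137 passed in opposite directions. Independent lists of the same sizes would share 3161.1 higher and 1397.5 lower genes. In 100 simulations of unchanged groups against these controls limma passed 0 genes in both, a number the adjusted threshold keeps near 0, which makes it no reference for the overlap of calls. Across genes, which are not independent replicates, the log2 fold changes of the lines had r = 0.934, against 0.578 (0.537 to 0.610) in the simulations, and shared their sign in 91.9% against 69.6%. Their covariance was 5.50 against a simulated 0.0575, a difference of 5.44. The simulated groups share the 2 controls, so the simulated covariance, 0.0522 to 0.0643, is what array noise in shared controls gives. That range argues against such noise as the source of the 5.44. Splitting the 2 controls would leave 1 array for each line and was not done. Any trait common to both controls is outside the simulations, so part of the excess may still come from the shared controls. Under housekeeping centring 9323 genes passed in the same direction, 2620 higher and 6703 lower.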

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

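The tests of both explanations for Dmrt1 and of the germ cell share were chosen only after the result was seen, and the test of X-linked Sertoli genes before.

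Genes differed between the Cre lines by limma's test of the difference itself, each given as the log2 value of Sf1-Cre minus Dhh-Cre. Lower in Sf1-Cre were Lpar3 (-8.31), Tsx (-7.09), Wfdc18 (-6.86), Tbx22 (-6.08), Cep85 (-5.88), Dmrt1 (-2.64), Sox9 (-1.96), Sox8 (-1.50), Aldh1a3 (-0.94), Actg2 (-0.78), Acta2 (-0.67), Dhh (-0.65) and Tgm2 (-0.49). Higher were Xaf1 (5.72), Ptchd3 (4.68), Glipr1l1 (4.50), Sfrp4 (4.48), Clec7a (4.47), Foxl2 (2.49), Kit (2.42), Foxl2os (1.87), Lyz2 (1.02), Nr5a1 (0.92) and Tyrobp (0.55). These are fitted values: for Lpar3, Tbx22, Xaf1, Glipr1l1, Clec7a and Kit the mean of 1 group lay under log2 4. For Xaf1 the other probe set gave -5.34, and for Cep85 it gave -0.19.

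Lists that differed between the lines by camera were the spermatid (median 2.12), granulosa (0.78), Leydig (0.68), macrophage (0.52) and cholesterol synthesis (0.40) lists, higher in Sf1-Cre. The spermatogonia (-0.97), retinoid (-0.94), peritubular (-0.67), proliferation (-0.60), tight junction (-0.59) and Sertoli (-0.51) lists were lower. With an estimated correlation camera called none of the 21 lists, and fry called 10.

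In 1 of 50 groups of 4 arrays checked, a sample stood apart from the others: Trp53tg5 lay at log2 3.82 in Sf1-Cre replicate 1 with the others from 2.54 upward, its gap to the nearest of them being 0.959 of the whole range. Chance picks out about 1 group in 20. All 4 values lie under log2 4.

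Probe sets without exactly 1 gene symbol, which enter no comparison of genes, also carried signal. Of 10143 such probe sets 51 of the array's control class were left out, and 3230 of the other 10092 were tested. Of the tested ones 51 were higher and 113 lower by at least 16-fold in Sf1-Cre than in control. In Dhh-Cre 33 were higher and 217 lower by as much.

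Dmrt1 was higher in the arrays labelled Dhh-Cre than in the controls, by 1.55 as deposited and 0.41 under housekeeping centring. An exchange of labels between these groups is argued against by Foxl2os, whose lowest Dhh-Cre value lay 7.09 above the highest control value. A larger share of Sertoli RNA after the loss of germ cell RNA is a candidate explanation, since the Dmrt1 change lay -0.38 from the median of the Sertoli list, inside its quartiles of 0.67 and 2.69. The change also lay inside the quartiles of other lists, such as the spermatogonia (0.64 and 1.70) and housekeeping (0.42 and 1.73) lists. The test of the Sertoli quartiles therefore does not single out Sertoli RNA. That test says nothing on whether the deletion took place, since the position of the probe set is not given in the sources used here. Samples from another line under this label, and an incomplete deletion, were not tested and stay open. Any Dmrt1 RNA of germ cells is part of the whole-testis signal and was not separated from that of Sertoli cells.

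The Sertoli list was lower and the granulosa list higher in Sf1-Cre than in the arrays labelled Dhh-Cre. A different share of germ cell RNA would move both the same way and is argued against as the sole cause: the array means of the lists moved by -0.97 (larger SD 0.067) and 0.849 (larger SD 0.256), 1.82 apart. The medians of their genes moved by -0.51 and 0.78. These are the values that showed the pattern, so they are no independent test of it. A few X-linked genes may account for part of the Sertoli difference, since without its 4 X-linked members the median was -0.28, between the bounds set in advance, so this stays open. The RNA of each group comes from whole testes, and whether genes changed within Sertoli cells or the number of those cells changed was not tested. The Actb 3' to 5' ratios of the 2 mutant groups overlapped, at 9.51 and 13.6 against 9.45 to 13.5.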

How the results depend on the processing

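Of 4404 values of 233 named gene results under the alternatives, 4297 (97.6%) kept their direction and side of the threshold, 84 no longer passed, 5 newly passed, 9 that passed before or after changed sign, and 9 changed sign without passing. Of 1383 values of 63 list results 1210 (87.5%) did so, 80 no longer passed, 31 newly passed, 15 that were called before or after changed the sign of their median, and 47 did so without a call. Of those 15, camera still called 11 up and no longer called 4. The cause was not tested for any value here, except that a stricter threshold calls fewer genes by construction. Leaving out an array moved gene counts in both directions. Housekeeping centring lowered genes by more than that list's own median fold change, taking it to -0.58 in Sf1-Cre and -0.46 in Dhh-Cre. Under housekeeping centring, Dmrt1 in Dhh-Cre against control was 0.408 and no longer passed. Among genes and lists that passed before or after, those that changed sign were Defb15 (-0.004), Figla (-0.198), Insig1 (-0.009), Kit (-0.786), Tsx (-0.269) and Zbtb16 (-0.385) in Dhh-Cre, and Defb15 (-0.203), Sox8 (-0.569), Sox9 (-0.328) and the median of the housekeeping list (-0.58) in Sf1-Cre, of which only Kit and Sox8 passed as lower. Centring on the peritubular and endothelial lists lowers every gene alike, here by more than the median fold change of either list. It turned the medians of 7 called lists negative in Sf1-Cre, the endothelial (-0.68), fibroblast (-0.252), housekeeping (-2.11), Leydig (-0.47), TGF-beta and activin (-0.495), theca (-0.953) and Wnt (-0.762) lists. In Dhh-Cre it did so for 7 called lists, the endothelial (-0.365), Leydig (-0.8), peritubular (-0.644), retinoid (-0.914), Sertoli (-0.755), TGF-beta and activin (-0.994) and Wnt (-0.363) lists. Camera still called 5 of these up in Sf1-Cre, not the housekeeping and theca lists, and 6 in Dhh-Cre, not the peritubular list. It compares a list with other genes that were lowered alike, so these kept calls are no separate support for a rise. Of lists not called, 4 medians in each line changed sign under housekeeping centring, and 7 in Sf1-Cre and 8 in Dhh-Cre under the other. With an estimated correlation camera called 0 lists in each of the 3 comparisons, where fry called 18, 18 and 10. In Dhh-Cre against control camera called 8 of 20 lists with the filter at log2 6 and 9 of 21 with the mean of all probe sets, against 12.

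Between the lines 3402 genes became 2101 at 2-fold or more, 1352 at adjusted p under 0.01 and 816 without the 3 arrays with Spink8 at log2 10 or above, an alternative chosen after seeing the data. Leaving out each array in turn gave 1234 (without Dhh-Cre replicate 1) to 3717 genes between the lines, 9746 to 11047 in Sf1-Cre, 10001 to 11082 in Dhh-Cre and 8697 to 9974 in both lines. It gave 6 (without Dhh-Cre replicate 1) to 11 lists between the lines, 11 to 12 in Sf1-Cre and 10 to 13 in Dhh-Cre. Dmrt1 ran from -1.221 to -0.945 in Sf1-Cre, 1.308 to 1.799 in Dhh-Cre and -2.89 to -2.398 between them. Where this left a group with 1 array, the lone array was assumed to vary like the other groups. With replicate numbers as a block, 9796, 10771 and 2967 genes passed; deviations of arrays sharing a number had r of -0.194 to 0.38, so the numbers were not taken as pairing. Signal over background limits folds: where a group mean lay under log2 4, folds are bounds.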

Other observations

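Among the tests below, those of gene families and proteasome genes were chosen only after their values were seen, as were those of X-linked genes in the 16-fold class in Dhh-Cre, in the 2-fold classes and between the lines. The matched draws and the 16-fold class in Sf1-Cre were chosen before.

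Genes of 219 families, grouped by symbol prefix with at least 8 tested members, were tested by camera as the lists were. Cfap genes, of cilia and the sperm tail, fell in 23 of 24 in each line, with medians of -2.34 in Sf1-Cre (adjusted p = 5.96e-05) and -4.25 in Dhh-Cre (adjusted p = 1e-06), and 14 were higher in Sf1-Cre than in Dhh-Cre. Annexin genes rose in 9 of 9 in Dhh-Cre (median 2.41, adjusted p = 0.0319) and 7 of 9 in Sf1-Cre (median 2.64, adjusted p = 0.0905, not called), where 2 fell under housekeeping centring. Chemokine genes of the Ccl family were higher in 6 of 12 in Sf1-Cre than in Dhh-Cre (median 1.03, adjusted p = 0.0106). Among them were Ccl6 at 1.93 and Ccl12 at 1.71, and Ccl27a and Ccl28, which fell against control in both lines. Against control, 5 Ccl genes rose and 4 fell in Sf1-Cre (median -0.07), and 4 rose and 5 fell in Dhh-Cre (median -0.64). Kallikrein genes were higher in 7 of 9 in Sf1-Cre than in Dhh-Cre (median 1.89, adjusted p = 0.0109), led by Klk1b1 at a fitted 2.96, its Dhh-Cre mean lying under log2 4. Against control, 4 of them rose and 4 fell in Sf1-Cre (median -0.97), and 2 rose and 5 fell in Dhh-Cre (median -3.07). Some members higher between the lines thus fell less rather than rose. The 1 family called lower in Sf1-Cre than in Dhh-Cre was Myh, with 6 of 8 genes lower (median -1.16, camera adjusted p = 0.0354). The macrophage list was also higher in Sf1-Cre than in Dhh-Cre (median 0.52), and whether the Ccl genes follow it was not tested. With an estimated correlation 0 families were called in any comparison, where the preset one called 7, 9 and 7.

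The immunoproteasome genes Psmb8, Psmb9 and Psmb10, picked after their values were seen, rose in both lines. All 18 macrophage genes rose in each line as well (medians 4.07 in Sf1-Cre and 3.47 in Dhh-Cre), and whether these rises are linked was not tested. The Psmb family of 10 genes that holds them was not called in either (adjusted p = 0.0905 in Sf1-Cre and 0.174 in Dhh-Cre). Psmb8, Psmb9 and Psmb10 were at 3.40 ± 0.30, 3.38 ± 0.24 and 3.41 ± 0.15 SE in Sf1-Cre and 2.89 ± 0.35, 2.81 ± 0.28 and 3.35 ± 0.17 SE in Dhh-Cre, and stayed at 1.67 or above under housekeeping centring. For Psmb8 and Psmb9 these are fitted values, with control means under log2 4. The subunit genes they replace in the constitutive proteasome, Psmb5, Psmb6 and Psmb7, were at 0.98, 0.39 and -0.01 in Sf1-Cre and at -0.17, -0.76 and -1.16 there under housekeeping centring. In Dhh-Cre they were at 0.79, 0.25 and 0.06, and at -0.36, -0.89 and -1.09 under that centring.

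The 465 tested X-linked genes were shifted up, with medians of 1.57 in Sf1-Cre and 1.92 in Dhh-Cre against 0.302 and 0.486 for autosomal genes. Lower signal of X-linked genes in the controls is argued against as the whole cause: the smaller excess over 10000 autosomal draws matched on control signal was 0.90, and 0 draws were as high. For loss of germ cells with a silent X chromosome, a bound was set in advance on falls of at least 16-fold in Sf1-Cre. The share of X-linked genes was not below that bound (36 of 465 against 719 of 13302, odds ratio 1.47, Fisher's exact p = 0.0374). In Dhh-Cre, for which no bound was set, the share was 40 of 465 against 1260 of 13302 (odds ratio 0.899, Fisher's exact p = 0.573). That class covers only the strongest falls, not the X-linked genes that rose, so the test cannot decide on this cause. The odds ratios for falls of at least 2-fold were 0.59 in Sf1-Cre and 0.445 in Dhh-Cre. Such values would follow from the upward shift itself, whatever its cause, so they are no test of that loss. Loss of germ cells with a silent X chromosome may account for part of the shift and stays open. Between the lines, X-linked genes made up 11 of the 26 at least 16-fold lower in Sf1-Cre (odds ratio 21.4, Fisher's exact p = 2.84e-10), which stays unexplained.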
